A study of Drosophila melanogaster with 18 samples.

How the data were processed

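STAP-seq was applied to Drosophila melanogaster S2 cells, an embryonic line with blood-cell-like properties, and to ovarian somatic cells. In this assay sheared genomic fragments are cloned into a reporter plasmid, with or without an enhancer, and the 5′ ends of the transcripts that start inside the fragments are sequenced, so that each fragment is tested for its own capacity to start transcription. Fragments were size-selected to about 100 to 250 bp, per the labels' protocols, and sites up to that distance apart can lie on 1 fragment. The labels describe 18 samples in 9 groups. The 8 samples behind the 2 lists used here are the genome-wide fragment library with the zfh1 enhancer (2 samples) and without an enhancer (2 samples), and a library of fragments from bacterial artificial chromosomes (BACs) with the zfh1 enhancer (3 samples) and without one (1 sample). The other 10 samples (BAC libraries with the sgl, ham, ncm and ssp3 enhancers in S2 cells, and with the tj enhancer in ovarian somatic cells, 2 samples each) were not analysed here.

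As deposited, each list is a BED-like table with the chromosome, a start and an end 1 base apart, a site name holding a serial number, and a strand. The lists hold no read count, level, enrichment or p-value, and no column for a sample, a replicate or a condition, so depth is unknown and no counting interval for a site's level can be given. The labels of the zfh1 and of the no-enhancer samples point to the same list in each library, and both lists are named for zfh1. How sites were called, filtered, merged or numbered is not given in the sources used here. Nor is whether replicates were pooled, or in which condition the sites were called. Per the submitters' processing notes the genome build was dm3, and CASAVA 1.9.1 and Bowtie 0.12.9 were named without a role. Positions are printed 1-based in dm3. The gene table at hand describes Release 6 of the genome, a different build, so no site was assigned to a gene, exon, intron or UTR.

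The tests planned before the data were examined assumed values per site. The comparison of zfh1 with no enhancer (in both libraries), the range of strengths, the gene lists, the position relative to annotation and the core promoter motifs could not be computed from positions and are not reported. The rule for naming sites also rested on values. In its place the sites numbered 1 to 5 in each list, the groups with the most sites and single regions are named. These were chosen after the lists were seen. Strand counts per chromosome, neighbours within 100 bp and 1000 bp, and sharing at the same base between the lists were fixed before the data were examined. The gaps that define chains and BAC regions, the range of 22 to 250 bp for pairs, the use of spans for rates, the 10 bins of serial numbers, the runs of numbers and their minimum of 40 sites, and the tests per region were set after the positions had been seen. The 2000 bp gap of chains was set after the gaps on XHet were known.

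From the lists the following was computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Strand use was tested per chromosome with an exact two-sided binomial test, Benjamini-Hochberg (BH) adjusted over the 12 chromosomes and scaffolds, with Wilson 95% intervals for shares. Rates per Mb are counts over the distance between the first and the last listed site, with exact Poisson 95% intervals; arm lengths of dm3 were not used. Chains are sites on either strand with gaps of at most 2000 bp. Pairs of sites 22 to 250 bp apart were classed as same-strand, divergent (minus-strand site to the left) or convergent, and set against 100 shuffles of the strands within each chromosome; clustering was set against 100 lists in which each site was moved at random by up to 50000 bp. BAC regions, for which the labels give no coordinates, were taken as stretches of the BAC list without a gap above 60 kb. Sites were called shared at the same base and strand, and alternatives allowed 5 or 50 bp; chance was estimated from 1000 lists in which each BAC site was moved by 500 to 5000 bp. Serial numbers at shared sites were compared by Pearson's r and Spearman's rho with 100000 permutations, whose smallest possible p is 1e-05. Runs are stretches of consecutive serial numbers over which the text order of chromosome and position only ascends; 5 text orders were tried and the one with the longest runs, chromosome, tab and 0-based start, was kept (926 runs, against 928 to 3808 for the others). Correlations of site numbers per region were set against regions of the same lengths at 1000 random places of the same arms. Median serial numbers of the 6 largest chains were set against 10000 random sets of sites each, two-sided, BH adjusted over the 6. Discordance by region was tested with Fisher's exact test, BH adjusted over the 34 regions. All these tests run across sites, which are not replicates of a sample and are not independent where they lie close together. Of these steps 7 were tested on simulated data and recovered what was planted: 300 of 300 shared sites among 600, 5 of 5 tie classes among 1610 sites, 200 of 200 divergent pairs among 2200 sites, a chain of 40 sites among 2037, 12 of 12 regions among 96 sites, 60 of 60 same-strand pairs at a planted distance among 2060 sites, and 20 of 20 related sets of 100 values called by the permutation test. The pairs and the chain were planted among evenly spaced sites and the regions without other sites, so the close neighbours of the real lists were absent. The permutation test was not run on unrelated values. For these steps the simulations show that planted signals are counted, and how often false calls arise was not tested. The strand tests, the moved lists and regions, the chain medians and the tests per region were not simulated.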

Results

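The study measured where transcription starts within fragments of the fly genome when the fragments sit in a plasmid with or without an enhancer, here that of zfh1, a gene for a zinc finger and homeodomain transcription factor. The genome-wide list held 13218 single-base initiation sites on 6 chromosome arms and 6 scaffolds named Het in dm3. The BAC list held 753 sites on 2L, 2R, 3L, 3R and X. The genome-wide list is named in the labels of 2 zfh1 and 2 no-enhancer samples, and the BAC list in those of 3 zfh1 samples and 1 no-enhancer sample. Each list is named for zfh1 and holds 1 set of sites, without replicates. The sites may have been called in the zfh1 samples alone, so they cannot be read as sites found with and without the enhancer. The lists give positions without levels, so the response to the enhancer, the spread between replicates and the strength of single sites have no values here, and the depth of the samples is unknown.

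The first question the genome-wide list answers is where in the genome fragments could start transcription. Chromosome arm 3R held the most sites, 3071 or 23.2% of the list, followed by 2R with 2574 and 3L with 2521. Arm 2L held 2134 sites, X held 2086 and the small chromosome 4 held 83. Per Mb between the first and the last site, 2R was the densest of the arms with 121.7 sites (95% Poisson interval 117.1 to 126.5). 3R followed with 110.3 (106.4 to 114.3) and 3L with 103.2 (99.2 to 107.3). The rates of X, 93.1 (89.1 to 97.2), and 2L, 92.9 (89.0 to 96.9), had overlapping intervals, and chromosome 4 had 70.5 (56.2 to 87.4). These intervals cover counting error only. How much of each arm or scaffold was covered by fragments or could be mapped is not known here, so a lower rate need not mean less initiation. The 749 sites on the Het scaffolds, which in dm3 carry mapped heterochromatic sequence, made up 5.67% of the list. 2RHet held 266 of them at 81.2 per Mb, 3RHet held 187 at 75.3, 3LHet held 181 at 71.5 and 2LHet held 26 at 81.5. XHet had the highest rate of all, 493.8 per Mb (389.7 to 617.2), from 77 sites on a span of 0.156 Mb; without a dense chain of 69 sites its rate was 57.4 per Mb (24.8 to 113.1), from 8 sites. YHet had the lowest rate, 37.4 per Mb (19.3 to 65.4), from 12 sites.

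**Figure D1:**
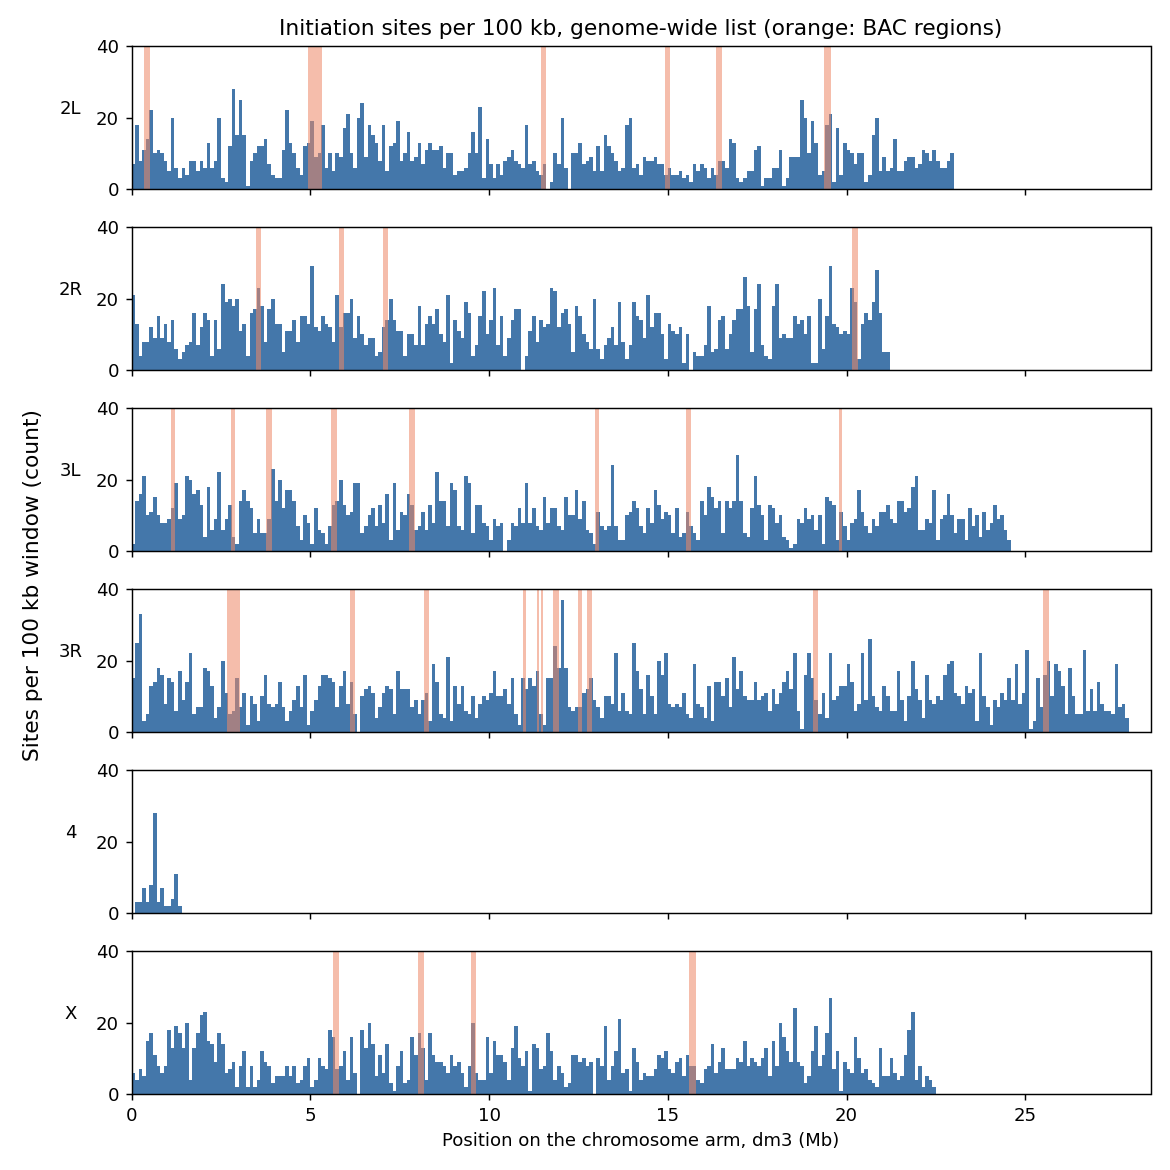
Number of initiation sites of the genome-wide list in each 100 kb window (bars, vertical axis in sites) along the 6 chromosome arms (horizontal axis, dm3 position in Mb), with the 34 BAC regions shaded. Windows that hold any site, scaffolds included, have a median of 9 sites, and few windows on the arms are empty.

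Sites were spread along the arms. The median gap between neighbouring sites on either strand was 5279 bp, and a 100 kb window with any site held a median of 9. The widest stretch between neighbouring sites was 169.9 kb on 2L, from 12167129 to 12337056, followed by 157.7 kb on X, from 6253582 to 6411316. At the other end, 69 sites lay in a chain of 13.8 kb on XHet, from 189291 to 203049, which was 89.6% of the sites on that scaffold. A chain of 25 sites covered 3.93 kb on chromosome 4, from 612039 to 615970, 30.1% of the sites of that chromosome. On 3R, 12 sites fell within 526 bp, from 26600484 to 26601009, and 11 of them were on the minus strand. Chains of 11 sites lay on 2RHet, from 2267121 to 2270973, and on X, from 21799849 to 21804858. With gaps of at most 1 kb the XHet chain shortened to 38 sites. In 100 lists with moved sites the largest chain held a median of 32 sites and at most 68. Moves reached up to 50000 bp and were turned back at the last listed site of XHet, 203049, where the chain ends. The chain's sites thus stayed close together, and these lists do not measure how often chance gives such a chain.

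Use of the strands over the whole list did not differ past the threshold, with 6622 plus-strand and 6596 minus-strand sites (50.1% plus, Wilson 95% interval 49.2 to 50.95, exact binomial p = 0.828). Of the 12 chromosomes and scaffolds, 1 departed from equal use after BH adjustment. XHet had 54 plus-strand and 23 minus-strand sites, 70.1% plus (59.2 to 79.2, exact binomial p = 0.000539, BH-adjusted 0.00647). Its dense chain held 48 plus-strand and 21 minus-strand sites, 89.6% of the scaffold's sites. The departure thus rests on 1 stretch of 13.8 kb, whose close sites are not independent. Outside the chain 6 of 8 sites were on the plus strand, too few sites for any split to pass the threshold. On 3LHet 41.4% of the sites were on the plus strand and on 3RHet 41.7%, both with an adjusted exact p of 0.112. None of the 6 arms passed the test; among them X had the smallest adjusted exact p, 0.302, with 51.8% plus.

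Sites had close neighbours far more often than random placement gave. In the genome-wide list 14.4% of the sites had another site on the same strand within 100 bp, against a median of 1.29% and at most 1.57% in 100 lists with moved sites. On the opposite strand 8.25% had one, against a median of 1.21% and at most 1.49%. The smallest distance between 2 sites on the same strand was 22 bp in both lists, while sites on opposite strands came as close as 1 bp in the genome-wide and 2 bp in the BAC list. The genome-wide list held 607 same-strand pairs at 1 to 50 bp, none of them closer than 22 bp. So sharp a limit points to a minimum distance set when the lists were made, by a rule that is not given. The moved lists had no such minimum, so the same-strand share is lowered relative to them. Within 1000 bp the shares were 26.0% for the same strand, against at most 12.7% in moved lists, and 20.7% for the opposite strand, against at most 12.4%. In the BAC list the shares within 100 bp were 11.6% for the same strand and 5.05% for the opposite strand.

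Opposite-strand neighbours were more often divergent than convergent. Of 944 opposite-strand pairs at 22 to 250 bp, 585 were divergent and 359 convergent, 62.0% divergent (58.8 to 65.0, exact binomial p = 1.87e-13). With shuffled strands the share lay between 45.2% and 54.2%. The difference was largest at 101 to 150 bp, with 154 divergent and 52 convergent pairs (BH-adjusted exact p = 3.92e-12), and it was also past the threshold at 51 to 100 bp, with 164 and 111 pairs (adjusted exact p = 0.00333), at 151 to 200 bp, with 107 and 53 (7.08e-05), and at 201 to 250 bp, with 69 and 39 (0.00754). Pairs at 1 to 50 bp, with 167 divergent and 186 convergent (0.406), and at 251 to 300 bp, with 25 and 26 (1), did not differ past it. A site can belong to more than 1 pair, so these pairs are not independent. The exact p-values are therefore likely too small and the interval around 62.0% too narrow. On the chromosome arms alone there were 540 divergent and 309 convergent pairs, so the pairs on the Het scaffolds showed no excess of divergent ones. Of all 2500 pairs at 22 to 250 bp, 37.8% were on opposite strands, below the 47.6% to 52.0% of the shuffled lists. The BAC list had 20 divergent and 14 convergent pairs, which did not pass the same test (58.8% divergent, 42.2 to 73.6, exact binomial p = 0.392). Its interval holds both an equal split and the 62.0% of the genome-wide list.

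**Figure D2:**
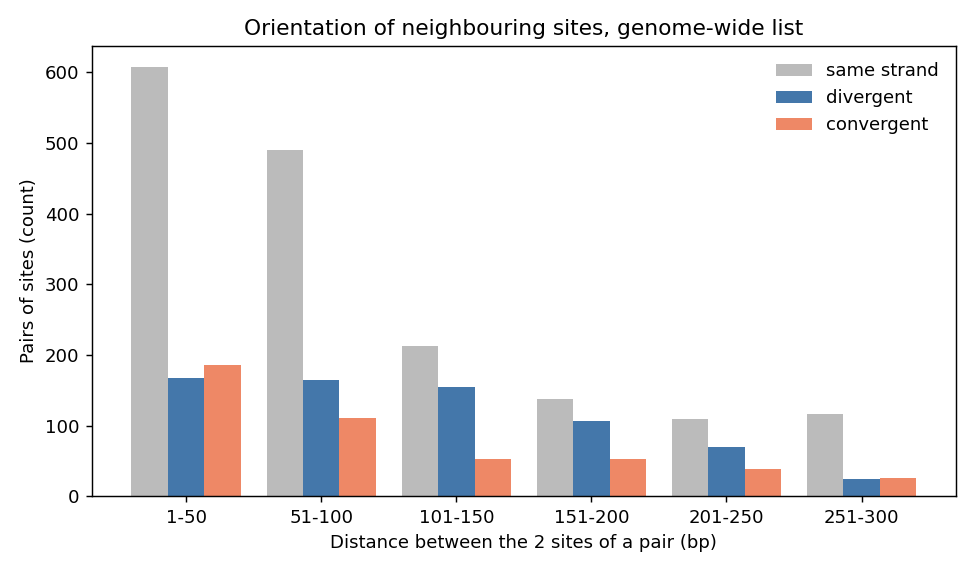
Number of pairs of sites in the genome-wide list (vertical axis) by the distance between them in bp (horizontal axis), for pairs on the same strand, divergent pairs and convergent pairs. Divergent pairs outnumber convergent ones from 51 to 250 bp, with 154 against 52 at 101 to 150 bp, and not at 1 to 50 or 251 to 300 bp.

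The BAC screen asked the same question of a small part of the genome, so its sites could be set against those of the genome-wide screen. The BAC list fell into 34 regions with a median length of 153.6 kb and 4.90 Mb in all, which held 656 genome-wide sites, 4.96% of that list. At the same base and strand, 406 sites were shared, 53.9% of the BAC sites (50.3 to 57.4) and 61.9% of the genome-wide sites in the regions (58.1 to 65.5). Each region starts and ends at a BAC site, so genome-wide sites between that site and the end of the insert are left out. Such sites cannot be shared, so the 61.9% may be too high and the number of sites in the genome-wide list alone too low. Lists with moved BAC sites shared 0.046 sites on average and at most 1, and no BAC site matched the same base on the opposite strand. Allowing 5 bp raised the shared BAC sites to 461 (61.2%), and allowing 50 bp to 479 (63.6%). Of these 479, 84.8% were at the same base, 55 were 1 to 5 bp away and 18 were 6 to 50 bp away. Counted at the same base, 347 sites in the regions were in the BAC list alone and 250 in the genome-wide list alone. Sites that differ by a few bp between the lists are not counted as shared in these numbers.

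Site numbers per region were correlated between the lists, which have the 406 shared sites in common. Across the 34 regions Pearson's r of the site numbers was 0.83 and Spearman's rho 0.87. Regions of the same lengths at 1000 random places of their arms gave a median r of 0.51 and at most 0.79, and a median rho of 0.53 and at most 0.83. Without the 2 regions farthest from the median r was 0.85. Per 100 kb the rho was 0.65, against at most 0.60 at random places. The r of 0.97 per 100 kb, against at most 0.96 at random places, rested on the 2 farthest regions and was 0.58 without them, against at most 0.53. Each of these 5 comparisons with random places had a one-sided permutation p of 0.001, the smallest that 1000 draws can give, and the same value after BH adjustment. The random places were drawn without regard to shared sites and are not bounded by BAC sites, so these values restate in part the sharing given above. Counted at the same base, the balance of sites in 1 list alone departed from that of the other regions in 3 regions. On 2L, 341433 to 524662, 37 sites were in the BAC list alone and 10 in the genome-wide list alone (Fisher's exact p = 0.00309, BH-adjusted over 34 regions 0.0487). On 3R, 8185736 to 8331514, these were 22 and 4 (Fisher's exact p = 0.0043, adjusted 0.0487). On 3R, 10957646 to 11032165, all 3 BAC sites were shared and 10 sites were in the genome-wide list alone (Fisher's exact p = 0.000149, adjusted 0.00507). That region depends on the gap of 60 kb. At 40 kb its BAC sites at 10976082 and 11032165 would not be joined, and whether a BAC covers the stretch between them is not given. BH adjustment ranks all 34 regions together, so the adjusted 0.0487 of the other 2 regions also rests on that region. With their unadjusted p-values as given, neither would pass the threshold if that region were left out of the adjustment.

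Every site carries a serial number, from 1 to 13218 in the genome-wide and from 1 to 753 in the BAC list, whose basis is not given in the sources used here. At the 406 shared sites the numbers of the lists went together, with Pearson's r of 0.59 and Spearman's rho of 0.63 (permutation p = 1e-05 for both). Within single arms the rho was 0.74 on 2L (82 sites), 0.63 on 2R (72 sites), 0.63 on 3L (76 sites), 0.52 on 3R (125 sites) and 0.65 on X (51 sites), each with a BH-adjusted permutation p of 1e-05. These are correlations across sites, which are not independent replicates.

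In the genome-wide list the numbers ran in stretches over which the text order of chromosome and start only ascended. There were 926 such runs, against a mean of 6604 with shuffled numbers, and the 34 runs of at least 40 sites held 9868 sites, 74.7% of the list. The last 19 of these 34 lengthened from each run to the next, from 74 sites up to 1034, 1475 and 2318. The BAC list had 117 runs, against a mean of 378 with shuffled numbers, and its last 4 runs of at least 40 sites held 47, 69, 84 and 129.

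**Figure D3:**
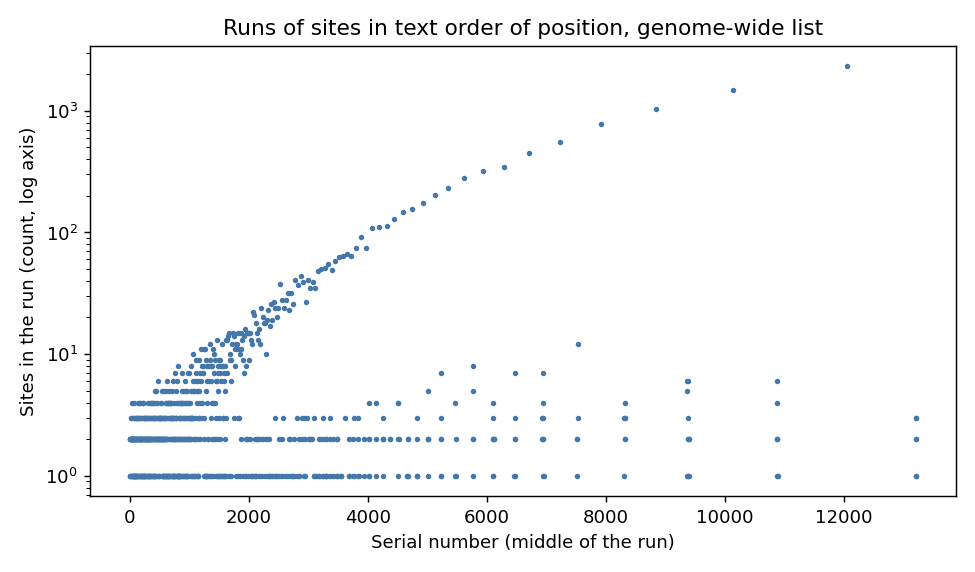
Number of sites in each ascending run of the genome-wide list (vertical axis, log scale, sites) against the serial number at the middle of the run (horizontal axis); each point is 1 of 926 runs. The longest runs lengthen with the number, up to 2318 sites, and short runs lie between them.

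Sites with low numbers were shared more often than sites with high numbers. Of the 10% of BAC sites with the lowest numbers 65.8% (54.6 to 75.5) were in the genome-wide list at the same base, and of the 10% with the highest numbers 25.3% (16.9 to 36.2; Fisher's exact p = 7.23e-07). Of the genome-wide sites in the BAC regions, 78.8% (67.5 to 86.9) of the lowest-numbered 10% and 24.6% (15.8 to 36.3) of the highest-numbered 10% were in the BAC list (Fisher's exact p = 4.06e-10). At the same base the share of BAC sites was highest, 74.7%, in numbers 152 to 226. Within 5 bp it was highest in numbers 1 to 76, at 98.7% (92.9 to 99.8) or 75 of 76 sites, and 26.7% in numbers 679 to 753. BAC sites 1 to 5 lay on 2L at 479682 (minus strand), on 2L at 490834 (plus), on 2R at 5866824 (plus), on 3R at 19171884 (minus) and on 2R at 20181625 (plus). Their nearest genome-wide sites were at offsets of -4, 0, -2, 1 and 1 bp along the direction of transcription. Genome-wide sites 1 to 5 lay outside the BAC regions, on 3R at 9638830 (plus), 2L at 14490863 (plus), 2L at 11081397 (minus), X at 6173301 (minus) and X at 11908458 (plus).

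**Figure D4:**
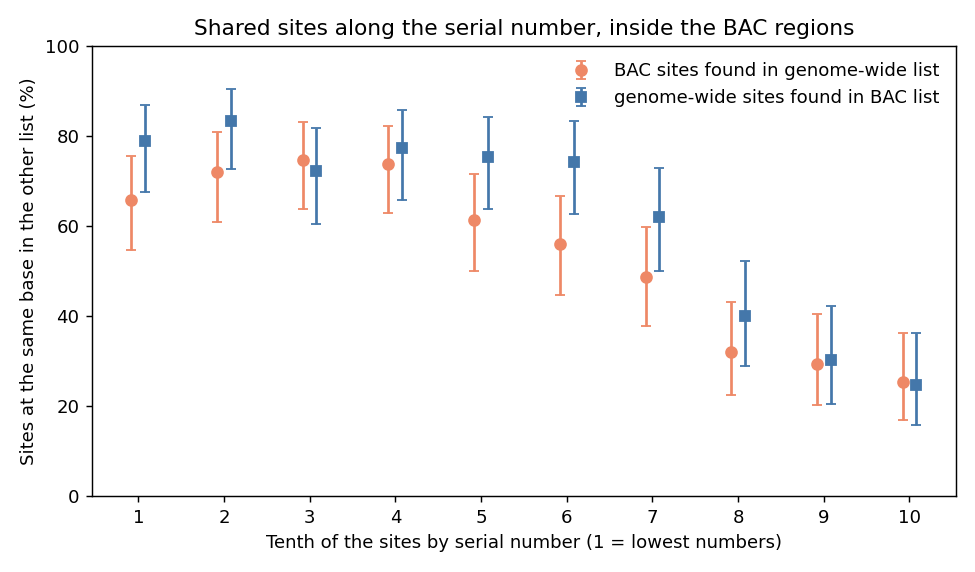
Share of sites found at the same base and strand in the other list (vertical axis, percent; bars are Wilson 95% intervals) over 10 bins of the serial number with nearly equal numbers of sites (horizontal axis, bin 1 holds the lowest numbers), for the 753 BAC sites and the 656 genome-wide sites inside the BAC regions. The share falls from 65.8% to 25.3% of the BAC sites and from 78.8% to 24.6% of the genome-wide sites between bin 1 and bin 10.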

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

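No paired analysis was possible because the lists hold no value for a sample, and for the same reason the alternatives fixed before the data were examined for replicate blocks, leaving out replicates, DESeq2, normalization, pseudocounts, filters on values, annotation distance, gene lists and motifs were not run. Only the distances of 5 and 50 bp and 1 site per cluster were fixed then; all other alternatives here were chosen after seeing the data, among them leaving out the 25% of sites with the highest serial numbers. Allowing 5 bp raised the shared share from 53.9% to 61.2% of BAC sites and from 61.9% to 70.1% of genome-wide sites, and 50 bp raised it to 63.6% and 73.3%. Without the highest-numbered 25% of sites 57.6% of BAC sites were shared. The Spearman rho of the numbers stayed between 0.58 and 0.63 in the 3 alternatives that change which sites are shared; other region gaps cannot change it. Without the highest-numbered 25%, 11.8% of genome-wide sites had a same-strand and 6.07% an opposite-strand neighbour within 100 bp, where removing sites by construction removes neighbours. In the BAC list these were 11.6% and 5.05%, and the cause was not tested. The divergent share was 63.6% on the main arms and 62.5% without the highest-numbered 25%, past the threshold in both, and 58.8% in the BAC list, where it was not, with 34 pairs instead of 944. The plus-strand share of all sites crossed the middle without the XHet chain, from 50.1% to 49.996%, neither past the threshold. On XHet it was 72.0% with same-strand clusters within 100 bp counted once and 74.5% without the highest-numbered 25%, both past the threshold. Without the chain it was 75% of 8 sites, too few for any split to pass the threshold. The XHet result thus rests on the chain's sites, and whether strand use departs outside the chain cannot be told. Without the highest-numbered 25%, 3LHet (37.5% plus) and 3RHet (37.9% plus) also passed the threshold, each with an adjusted exact p of 0.0183. With gaps of 1 kb the largest chain held 38 sites and with 5 kb 72, on XHet in both.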

Other observations

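Of the tests in this part, that of close BAC pairs was written down before its result was seen; all others were chosen after the pattern or its values had been seen, including those of regular spacing and of the median numbers of the chains.

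Among the lowest-numbered 10% of BAC sites, 25 of the 75 with a genome-wide site within 5 bp differed from it by 1 to 5 bp, against 1 of 20 among the highest-numbered 10% (Fisher's exact p = 0.0108, BH-adjusted over both lists 0.0216). For genome-wide sites in the BAC regions these were 11 of 63 and 1 of 17, which did not differ past the threshold (Fisher's exact p = 0.444).

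The ascending runs of serial numbers exclude an order by genome position alone. Sorting in the text order used here would make 1 run in place of 926. Sorting by numeric position would break runs only where the chromosome or the number of digits changes. The runs are consistent with sites sorted by a quantity with many ties at its low end, and the test written first, on BAC pairs at most 50 bp apart on a strand with 1 shared member, could not decide whether low numbers mark stronger sites: the shared site had the lower number in 5 of 6 pairs (83.3%, exact binomial p = 0.219). What the numbers rank stays open. No biological explanation was tested.

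In the genome-wide list 57 same-strand pairs lay 27 bp apart, against a mean of 19.6 ± 5.90 (SD) over the other 28 distances from 22 to 50 bp, and 31 bp, with 36 pairs, was the other distance past the same test (exact Poisson p = 0.0324, Bonferroni-adjusted). The count at 27 bp lay above a Poisson count around the mean of the other distances (exact Poisson p = 1.64e-10, Bonferroni-adjusted over 29 distances). That test takes pairs as independent, and the counts at the other distances spread more widely than Poisson counts. The p is therefore likely too small. A pile-up at the smallest same-strand distance, as merging of nearby sites could leave if the authors used it, was not seen at 22 bp, with 16 pairs against a mean of 21.1 over the other distances, but is not excluded (exact Poisson p for more pairs 0.893 and for fewer 0.157). Copies of 1 repeated element with a further listed site at a fixed distance are argued against, since at most 2 of the 57 pairs shared such an offset within 2000 bp. A further site in repeated sequence that could not be mapped would escape this count, and how such sequence was mapped is not given. A repeated element with just these sites, or a sequence feature, may account for the distance and was not tested.

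The chains with the most sites lay on XHet (69 sites), chromosome 4 (25 sites) and 3R (12 sites). For the listed sites, a tandem repeat with 1 regular spacing is argued against on XHet, where at most 6 same-strand pairs shared a distance within 2 bp, with a median of 5 and at most 8 in random placements. Sites in copies that could not be mapped would be missing from this count. More copies of that sequence in the library or the cells stay open: the chain's median serial number was 7513, against 6609.5 for all sites (two-sided permutation p = 0.259, BH-adjusted over 6 chains 0.777), and reading it as abundance assumes that low numbers mark abundant sites, which is not known. For the 3R chain, whose median of 2721 did not pass the threshold either after adjustment (two-sided permutation p = 0.016, adjusted 0.096), transcripts that start in the zfh1 enhancer carried on every zfh1 plasmid are a candidate source, an idea from general knowledge of the gene, which lies on 3R in the Release 6 gene table, and not from the lists. The BAC list held 0 sites in that chain, which decides nothing, since whether BAC sites were called outside the cloned inserts is not given in the sources used here, and the enhancer's dm3 position was not used here.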
